A study of Sus scrofa with 6 samples.

How the data were processed

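RNA of porcine ovarian follicles was measured on 6 single-channel Affymetrix porcine arrays, 2 for each of 3 stages. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cRNA was prepared from 6 µg of it by the manufacturer's protocol. Per the submitters' processing notes, the array software GCOS produced the values; its version and settings are not given in the sources used here. The deposited table holds a linear intensity for each probe set, with no detection call used here. The authors had scaled each array by 1 factor, since the mean of the deposited intensity values without the lowest and highest 2% was 500.1 on every array, and the values ranged from 0.1 to 47773. No further step between arrays could be seen in the values. Samples were assigned to stages by their titles. A separate description attached to the samples calls all 6 primordial, which conflicts with the titles, so the stage names rest on the titles alone.

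The table holds 24123 probe sets. The 124 control probe sets were left out of the tests, and of the other 23999 the platform annotation gives 1 gene symbol for 10069, several for 198 and none for 13732. The single symbols name 6765 genes, and 9961 of those probe sets matched the RefSeq gene table by gene identifier, which changed 0 symbols. Genes are named only from probe sets with 1 symbol. The annotation can be old, and a symbol such as AMELX is that of the annotation.

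Values were analysed as log2(signal + 16), with no further normalization. The 40% of probe sets with the lowest mean signal over the 6 arrays, those under 91.3, were left out, which left 14399, of which 6961 have 1 symbol and represent 5432 genes. The pseudocount of 16 limits the fold of a gene near the floor; 12.8% to 18.0% of all probe sets per array had a signal of 16 or less. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend) to all 6 arrays together, without a replicate block, so that the stages shared 1 estimate of the spread, with 3 residual and 6.33 prior degrees of freedom. Contrasts were middle minus primordial, last minus middle, last minus primordial, and middle minus the mean of the other stages, with limma's F-test for any stage difference. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the probe sets tested, with a threshold of 0.05. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to read tables and draw figures.

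Gene lists were tested with camera at its preset correlation of 0.01, taking for each gene the probe set with the highest mean signal, for lists with at least 4 tested genes, and adjusting over all lists and the 3 pairwise comparisons together. Of 28 lists, 27 could be tested; the erythroid list had too few genes. The lists covered the oocyte, granulosa, theca, stromal fibroblasts, smooth muscle and pericytes, endothelium, immune cells and surface epithelium; steroidogenesis, cholesterol synthesis, basement membrane, matrix turnover and the ovulatory response; TGF-beta and BMP signalling, the IGF, insulin and PI3K pathway, the Hippo, Notch and Wnt list, mitosis and DNA replication; oxidative phosphorylation, glycolysis, ribosomal proteins, antioxidant and detoxification genes, endoplasmic reticulum stress and chaperones, immediate-early and stress genes, apoptosis and atresia, hypoxia and VEGF, and complement and acute phase genes. Some lists share genes. The median, mean and camera direction of a list did not all have the same sign for the granulosa and Hippo, Notch and Wnt lists in middle minus primordial, the granulosa list in last minus middle, and the TGF-beta and BMP, antioxidant and ribosomal lists in last minus primordial; none of these passed. Where a gene had more than 1 tested probe set, probe sets were called in opposite directions for 38 of 1185 genes in middle minus primordial, 2 in last minus middle and 8 in last minus primordial. Genes of the lists among them included HSPA8, FST, CTNNB1, GSTA1, TXN and RPL23 in middle minus primordial and TPM2 in last minus middle.

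The lists, the tests, their alternatives and the rule for naming genes were fixed before the data were examined. The rule named, in each pairwise comparison, the 10 genes with the largest difference in each direction among called probe sets with 1 symbol whose replicates did not overlap between the stages, the 5 in each direction for the middle stage against the mean of the others, up to 4 members with the smallest p from each list, and 12 genes in any case. From the list members the text gives examples. With 2 arrays against 2, replicates of a probe set without any difference fail to overlap by chance in 33.3% of cases. Control transcripts were used to describe RNA quality, as the log2 difference of the 3′ and 5′ signal.

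The fit was tested on simulated data drawn from the real means and spreads, with known changes added in the middle arrays. For middle minus primordial over 14399 probe sets, 12 of 65 2-fold changes (18.5%), 44 of 63 4-fold changes (69.8%) and 58 of 64 8-fold changes (90.6%) were recovered, with mean estimates of 0.91, 1.96 and 3.05 on the log2 scale, and 3.4% of all calls were false. A 2-fold difference can therefore be missed. Few probe sets were changed in this simulation, whereas 47.4% were called in the real comparison, so its adjusted threshold was stricter. The shares recovered do not carry over to the real data. For last minus primordial over 5409 genes, a simulated list of 20 genes shifted by 2-fold was called by camera (adjusted p = 5.11e-29) and had an adjusted p of 0.0991 with an estimated correlation, and 0 of 40 lists without a shift were called. A true list shift can thus miss the threshold with an estimated correlation at this number of arrays. The simulated genes varied independently of each other. The 0 calls among lists without a shift therefore cannot show how the preset correlation performs with correlated genes.

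Alternatives were a pseudocount of 1 or 64, no filter or a filter of 60%, quantile normalization, centring each array on its median, eBayes without a trend, a replicate block, leaving out each array in turn, fitting only the 4 arrays of the stages compared, and a minimum difference of 2-fold; for lists also an estimated correlation, the mean of all probe sets of a gene, and fry. Fits without an array kept the probe sets of the full data, and a stage left with 1 array was assumed to vary like the others.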

Results

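Transcript levels were measured in ovarian follicles of prepubertal gilts (young female pigs that have not reached puberty) on an Affymetrix porcine expression array. Follicles had been isolated by morphology and diameter at 3 developmental stages, called primordial, middle and last by the submitters, with the aim of describing expression through the growth phase. Each stage had 2 arrays, titled as biological replicates, which gave 6 arrays in all. Nothing in the sources used here says whether the replicates came from separate animals, so the p-values measure only the spread between these samples. The median probe set signal was 119.3 and 125.4 on the arrays labelled primordial, 169.9 and 165.0 on the middle arrays and 140.3 and 150.6 on the last arrays. With 2 arrays per stage, the number of arrays limits the precision.

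Arrays of a stage resembled each other more than arrays of other stages. Across probe sets, Pearson's r of log2 signals was 0.972 between the arrays labelled primordial, 0.968 between the middle arrays and 0.964 between the last arrays, and 0.862 to 0.935 between arrays of different stages. Probe sets are not independent replicates, so these correlations describe the arrays only. The first principal component held 55.1% of the variance and ran from the arrays labelled primordial to the middle arrays, with the last arrays between them. The second held 22.4% and set the last arrays apart. A stage difference of any kind was called for 7242 of 14399 probe sets (50.3%) by limma's F-test at an adjusted p under 0.05.

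All differences below are on the log2(signal + 16) scale, given ± the standard error of the fit with n = 2 arrays per stage, and folds are on the same scale, which understates the change of dim genes. The median difference over all probe sets tested was 0.22 for middle minus primordial, -0.07 for last minus middle and 0.14 for last minus primordial, and small differences should be read against these shifts. Over the 5432 genes of the list tests, at 1 probe set per gene, the median was 0.06 for middle minus primordial and for last minus primordial.

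The genes chosen in advance described the follicle's cell types. Transcripts made by the oocyte were highest in the middle arrays. ZP3, a glycoprotein of the zona pellucida, had a mean signal of 71.4 in the arrays labelled primordial, 2531 in the middle arrays and 120 in the last arrays, and GDF9, a growth factor secreted by the oocyte, had 144, 1414 and 182. AMH, made by granulosa cells of small growing follicles, was also brightest on the middle arrays, with 236, 1367 and 110. INHA, the alpha subunit of inhibin, was high at both ends, with 13718 in the arrays labelled primordial and 13989 in the last arrays against 3021 in the middle arrays. LHCGR, the luteinizing hormone receptor, had 1109, 713 and 5388, the last of these from arrays at 3367 and 7409. STAR, which brings cholesterol into mitochondria for steroid synthesis, had 27, 76.2 and 2057, and CYP17A1, the androgen-forming enzyme of theca cells, had 25.2 (from arrays at 40.2 and 10.3), 54.5 and 544. FSHR, the follicle-stimulating hormone receptor, had 283, 312 and 142. The probe sets of CYP19A1, BMP15, KITLG and FOXL2 fell below the filter on dim probe sets. Without that filter BMP15, another oocyte growth factor, was higher in the middle arrays than in those labelled primordial by 3.04 ± 0.52 (limma adjusted p = 0.00355), with a mean signal of 221 against 14.7, the latter from arrays at 4.3 and 25.1. No difference of CYP19A1, KITLG or FOXL2 passed the threshold in the 3 pairwise comparisons. Their mean signals over all arrays were 29.0, 57.6 and 24.5.

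**Figure D1:**
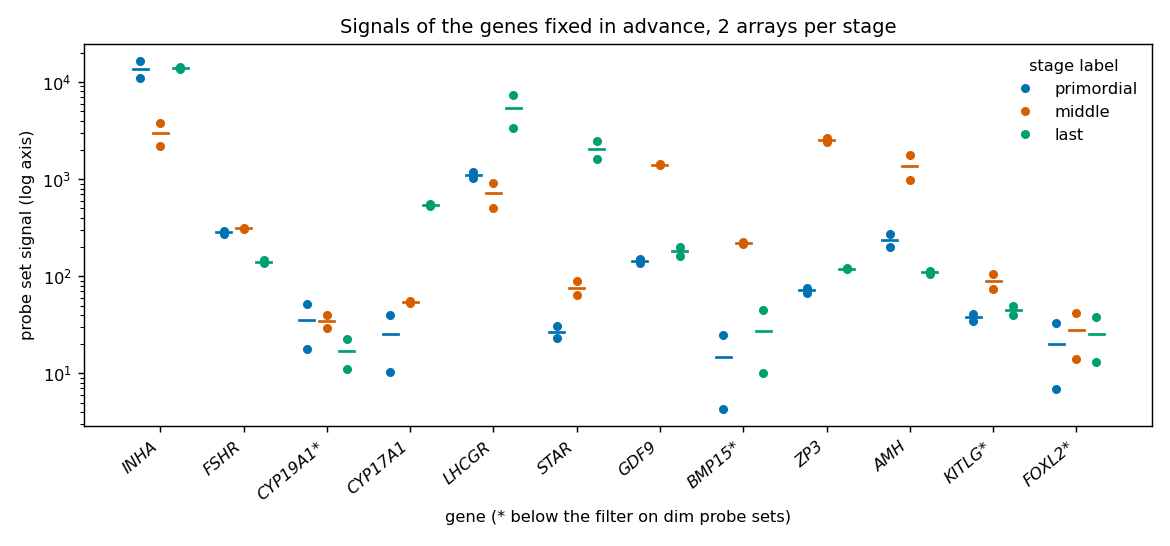
Probe set signal on a log axis for the 12 genes chosen in advance, with a point for each array, a bar for the mean of the 2 arrays of a stage and a colour for each stage label. ZP3, GDF9 and AMH were brightest on the middle arrays, with mean signals of 2531, 1414 and 1367, while STAR and CYP17A1 were brightest on the last arrays, with 2057 and 544.

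The comparison of middle with primordial follicles asked what distinguished the arrays labelled middle from those of the stage labelled as the earliest. At 1 probe set per gene, most genes of the oocyte list were higher in the middle arrays. All tested genes of the immune list and of the immediate-early and stress list were lower. HSPA8, of the latter list, also had a probe set called higher. With an estimated correlation the adjusted p was 0.239 for the oocyte and immediate-early lists and 0.449 for the immune list. DPPA5, a gene of germ cells and pluripotent cells, was higher by 7.50 ± 0.27 (limma adjusted p = 7.27e-07), from a mean signal of 5.6 to 3897. CXCL8, a chemokine that attracts neutrophils, was lower by the largest amount, at -8.47 ± 0.24 (adjusted p = 1.9e-07), from 10273 to 13.3. Of 14399 probe sets, 6821 (47.4%) were called, 4275 higher and 2546 lower in the middle arrays. Among genes with a probe set of their own, taken at 1 probe set per gene, 1245 were higher and 1224 lower of 5432. With each array centred on its median, 47.5% of the calls were higher, and with quantile normalization 52.5%, against 62.7% as deposited. The balance of directions over probe sets therefore depends on the scaling. It also depends on which probe sets are counted. At the deposited scaling 65.3% of the calls were higher with no filter and 57.1% with the 60% filter. Without middle replicate 1, 4356 probe sets were called.

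Among the 10 largest increases in the middle arrays were further genes of the oocyte and early embryo. ZP4 and ZP2, zona pellucida glycoproteins, were higher by 5.91 ± 0.23 and 5.71 ± 0.27. KPNA7, an importin of oocytes and early embryos, was higher by 5.96 ± 0.40, PADI6, a component of the oocyte's cytoplasmic lattices, by 5.41 ± 0.42 and WEE2, a kinase that holds the oocyte in meiotic arrest, by 5.04 ± 0.28. Of the remaining genes of the 10, SPARCL1 was higher by 6.32 ± 0.54, the proteoglycan DCN by 5.34 ± 0.23, the cadherin CDH11 by 5.19 ± 0.29 and the growth factor PTN by 5.01 ± 0.32. The adjusted p of these 9 genes ranged upward from 9.39e-07 for ZP4 to 3.76e-05 for SPARCL1.

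The 10 largest decreases included several cytokines. The chemokines CCL3L1, CCL4 and CCL5 were lower in the middle arrays by -8.02 ± 0.33, -6.48 ± 0.26 and -6.16 ± 0.67. The cytokine IL1B was lower by -5.78 ± 0.23, from a mean signal of 14032 to 244, and SPP1, osteopontin, by -6.07 ± 0.20, from 20793 to 295. FABP4, a fatty acid binding protein of adipocytes and macrophages, differed by -7.18 ± 0.37, ARG1, arginase, by -6.31 ± 0.21 and the epidermal growth factor family member AREG by -5.92 ± 0.36. The probe set annotated to AMELX, an enamel protein gene, differed by -6.56 ± 0.51. The adjusted p was highest for CCL5, at 0.000123.

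Of 27 gene lists fixed in advance, 9 passed the threshold in this comparison by camera with its preset correlation, 2 higher and 7 lower in the middle arrays. None passed with an estimated correlation, with which 4 had an unadjusted p under 0.05; fry, which does not compare a list with other genes, called 14. In the oocyte list 8 of 12 genes on the array passed the filter, which a gene bright only in the middle arrays can do. Of these 8 genes 7 were higher and 0 lower, or 8 higher when adjusted over the list alone. Their median was 4.95 (camera adjusted p = 5.81e-07, and 0.239 with an estimated correlation). In the list of stromal fibroblast genes 9 of 13 were higher, or 10 adjusted over the list alone, with a median of 2.01 (adjusted p = 0.00015; adjusted p = 0.239 with an estimated correlation). FAP was higher by 3.96 ± 0.29 and COL6A3 by 3.82 ± 0.29.

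All 17 immune genes tested were lower in the middle arrays, also when adjusted over the list alone, with a median of -3.29 (adjusted p = 2.34e-07; adjusted p = 0.449 with an estimated correlation). CD53 differed by -5.17 ± 0.40, TYROBP by -3.75 ± 0.31, LAPTM5 by -3.66 ± 0.34 and AIF1 by -3.51 ± 0.42, all genes of leukocytes. At 1 probe set per gene, all 17 immediate-early and stress genes were lower too, with a median of -1.69 (camera adjusted p = 1.26e-10, and 0.239 with an estimated correlation). For HSPA8, a member of this list, tested probe sets were called in both directions. The transcription factors KLF4 and ATF3 differed by -4.61 ± 0.23 and -4.57 ± 0.22, and GADD45B by -3.50 ± 0.21. Of 17 genes of endoplasmic reticulum stress and chaperones, 15 were lower, also over the list alone, with a median of -1.21 (adjusted p = 5.81e-07; adjusted p = 0.239 with an estimated correlation), among them SDF2L1 at -2.87 ± 0.26, DNAJB9 at -2.83 ± 0.21 and ATF4 at -2.37 ± 0.17. Among the signs of RNA quality, the actin control moved with these groups, while GAPDH did not and EF1A stayed within its spread. The 3′ signal of the actin control exceeded its 5′ signal by 4.60 ± 0.54 (log2, SD, n = 2) in the middle arrays and 3.38 ± 0.25 in the arrays labelled primordial. For the GAPDH control the excess was 3.04 ± 0.35 and 3.06 ± 0.53, and for EF1A it was 1.10 ± 0.33 and 0.84 ± 0.24.

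Of 12 matrix turnover genes 9 were lower in the middle arrays, also over the list alone, with a median of -1.27 (adjusted p = 0.00112; adjusted p = 0.239 with an estimated correlation). PLAU, urokinase, differed by -3.82 ± 0.33 and the protease inhibitor TIMP2 by -2.30 ± 0.20. Of 10 genes of the hypoxia and VEGF list 7 were lower and 1 higher, or 7 and 2 over the list alone, with a median of -1.04 (adjusted p = 0.0151; adjusted p = 0.247 with an estimated correlation), with ADM at -3.87 ± 0.32 and ANGPTL4 at -3.50 ± 0.24. Of 15 glycolysis genes 9 were lower and 1 higher, also over the list alone, with a median of -0.75 (adjusted p = 0.0278; adjusted p = 0.483 with an estimated correlation). SLC2A1, a glucose transporter, differed by -2.21 ± 0.23 and LDHA by -1.87 ± 0.24, while PFKM was higher by 1.18 ± 0.26. In the ovulatory response list 4 of 8 genes were lower and 2 higher, also over the list alone, with a median of -1.22 (adjusted p = 0.0445; adjusted p = 0.434 with an estimated correlation). CEBPB differed by -4.56 ± 0.20 and the prostaglandin synthase PTGS2 by -4.28 ± 0.38, while PTX3 was higher by 2.49 ± 0.30. The glycolysis call was lost without primordial replicate 2 and without middle replicate 1 (adjusted p = 0.0502 in each, with a median of -0.46 in the latter), with the 60% filter (0.0692), with quantile normalization (0.0729) and by fry (0.0585), in a range from 0.0123. The ovulatory call was lost without middle replicate 2 (adjusted p = 0.118), last replicate 1 (0.0507) and last replicate 2 (0.0509). It was also lost with a replicate block (0.0557), with each array centred on its median (0.104), with the 60% filter (0.215), with the mean of probe sets (0.0536) and with a pseudocount of 1 (0.0599), in a range from 0.0045.

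The other 18 lists did not pass. Granulosa genes went both ways, with 5 of 16 higher and 6 lower (adjusted p = 0.796). NR5A2, a nuclear receptor needed for ovulation, differed by -4.56 ± 0.24, the aromatase gene CYP19A3 by -2.56 ± 0.18 and INHA by -2.20 ± 0.26, while NR0B1 was higher by 3.54 ± 0.39 and AMH by 2.41 ± 0.31. In the theca list 5 of 8 were higher and 1 lower (adjusted p = 0.131), with INSL3 higher by 2.36 ± 0.29 and CYP11A1 at -3.04 ± 0.50. The steroidogenesis list had 3 of 16 higher and 7 lower (adjusted p = 0.283), cholesterol synthesis 1 of 13 higher and 5 lower (0.131), smooth muscle and pericytes 5 of 12 higher and 1 lower (0.0769), endothelium 2 of 12 higher and 1 lower (0.583) and surface epithelium 3 of 4 higher (0.0564). Basement membrane had 3 of 6 higher and 1 lower (0.376), TGF-beta and BMP signalling 2 of 18 higher and 4 lower (0.258), IGF, insulin and PI3K signalling 5 of 14 higher and 1 lower (0.229) and the Hippo, Notch and Wnt list 3 of 9 higher and 4 lower (0.806). Mitosis had 2 of 18 higher and 2 lower (0.796), DNA replication 4 of 12 higher (0.251), oxidative phosphorylation 8 of 31 higher and 4 lower (0.18), ribosomal proteins 6 of 55 higher (0.117), antioxidant and detoxification genes 5 of 24 higher and 10 lower (0.139), apoptosis and atresia 2 of 6 lower (0.146) and complement and acute phase genes 6 of 12 higher and 3 lower (0.356). STAR was higher by 1.09 ± 0.31 (adjusted p = 0.0158), a call that ended without primordial replicate 2 (0.96, adjusted p = 0.0746), without middle replicate 1 (0.90, 0.103) with quantile normalization (0.35, 0.394), with a pseudocount of 64 (0.62, 0.0608) and in the fit of 4 arrays (adjusted p = 0.0889), over a range of 0.00851 to 0.394. FSHR, LHCGR and CYP17A1 did not pass, at 0.13 ± 0.23, -0.68 ± 0.37 and 0.88 ± 0.40 (adjusted p = 0.666, 0.16 and 0.101). Without primordial replicate 1 CYP17A1 passed, at 1.42 (adjusted p = 0.0213, in a range of 0.0213 to 0.823 over the alternatives). The sign of the FSHR difference changed with quantile normalization (-0.17) and with each array centred on its median (-0.11).

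**Figure D2:**
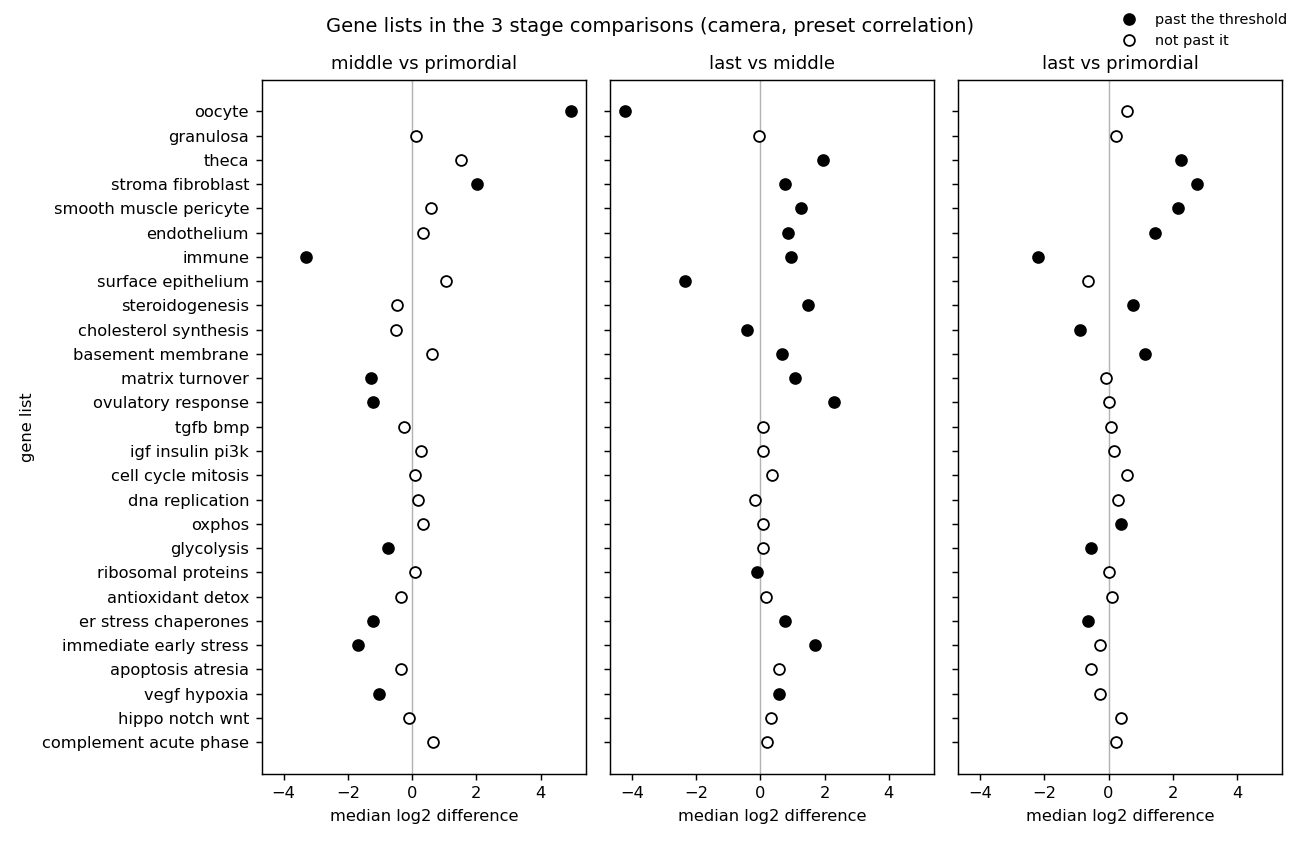
Median log2 difference of the tested genes of each list (horizontal axis) for the 27 lists and the 3 stage comparisons. Filled points passed the threshold by camera with the preset correlation (9, 16 and 11 lists from left to right) and open points did not.

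The comparison of last with middle follicles covered the end of the growth phase. Most genes of the oocyte list were lower in the last arrays, and most genes of the steroidogenesis, smooth muscle and immediate-early lists were higher. As lists these 4 had an adjusted p of 0.239 with an estimated correlation. NR5A2 was higher by 5.84 ± 0.24 (limma adjusted p = 5.28e-06), from a mean signal of 161 to 10142, and ZP2 differed by -5.13 ± 0.27 (adjusted p = 9.46e-06), from 2000 to 41.4. Of 14399 probe sets, 2481 (17.2%) were called, 1050 higher and 1431 lower, and of 5432 genes 478 were higher and 393 lower. The count rests on the middle arrays: 727 probe sets were called without middle replicate 1 and 1440 without middle replicate 2. Of the calls, 54.8% were higher with each array centred on its median and 42.3% as deposited.

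NR5A2 headed the 10 largest increases. ACTG2, an actin of smooth muscle, was higher by 5.54 ± 0.31 and STAR by 4.47 ± 0.31. The transcription factors ATF3, KLF4 and CEBPB were higher by 4.40 ± 0.22, 4.21 ± 0.23 and 3.74 ± 0.20, and DNAJB1 by 3.71 ± 0.23. RGCC was higher by 3.90 ± 0.57, the chemokine CXCL2 by 3.82 ± 0.29 and TP53INP2 by 3.62 ± 0.55. Among these genes the adjusted p was highest for TP53INP2, at 0.00243. ATF3, KLF4, CEBPB, DNAJB1, CXCL2, RGCC and TP53INP2 had higher mean signals in the arrays labelled primordial than in the last arrays. Among the 10 largest decreases were the oocyte genes ZP2, ZP4, DPPA5, PADI6, KPNA7 and ZP3, with -5.05 ± 0.23 for ZP4, -4.85 ± 0.27 for DPPA5, -4.82 ± 0.42 for PADI6, -4.44 ± 0.40 for KPNA7 and -4.23 ± 0.22 for ZP3. The others were C7H6orf52 at -5.10 ± 0.46, the complement regulator CD55 at -4.88 ± 0.25, the receptor GPR160 at -4.46 ± 0.48 and the lipase PNPLA4 at -4.24 ± 0.36.

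By camera with its preset correlation 16 of 27 lists passed, 12 higher and 4 lower in the last arrays. With an estimated correlation 0 passed, with 7 at an unadjusted p under 0.05, and fry called 15. In the oocyte list 7 of 8 genes were lower and 0 higher, also over the list alone, with a median of -4.22 (adjusted p = 6.07e-11; adjusted p = 0.239 with an estimated correlation), H1FOO, an oocyte linker histone, at -4.22 ± 0.29. All 4 surface epithelium genes were lower, also over the list alone, with a median of -2.33 (adjusted p = 0.00013; adjusted p = 0.239 with an estimated correlation), KRT8 at -2.59 ± 0.27 and EPCAM at -2.67 ± 0.34.

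Genes of steroid synthesis were higher in the last arrays. Of 16 steroidogenesis genes 12 were higher and 1 lower, or 13 and 1 adjusted over the list alone, with a median of 1.48 (adjusted p = 5.81e-07; adjusted p = 0.239 with an estimated correlation). CYP19A3 was higher by 3.12 ± 0.18 and FDX1, the electron donor of mitochondrial steroid enzymes, by 1.97 ± 0.20, while HSD17B7 differed by -2.11 ± 0.21. In the theca list 5 of 8 were higher and 0 lower, also over the list alone, with a median of 1.96 (adjusted p = 0.00741; adjusted p = 0.239 with an estimated correlation). CYP17A1 was higher by 2.99 ± 0.40, LHCGR by 2.84 ± 0.37 and INSL3 by 2.24 ± 0.29. In the ovulatory response list 6 of 8 were higher, also over the list alone, with a median of 2.30 (adjusted p = 3.85e-06; adjusted p = 0.239 with an estimated correlation), ADAMTS1 by 2.37 ± 0.18 and PTGS2 by 2.65 ± 0.38. Of 13 cholesterol synthesis genes 4 were lower and 1 higher, or 5 and 1 over the list alone, with a median of -0.43 (adjusted p = 0.0352; adjusted p = 0.676 with an estimated correlation), FDFT1 at -1.26 ± 0.17. Its median was -0.67 without middle replicate 1 and -0.18 without middle replicate 2. The call was lost without middle replicate 2 (adjusted p = 0.327) and without last replicate 2 (0.0545) and by fry (0.148), in a range from 0.00291.

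Of 12 smooth muscle and pericyte genes 8 were higher, or 9 over the list alone, with a median of 1.25 (camera adjusted p = 5.81e-07, and 0.239 with an estimated correlation). CNN1 was higher by 2.46 ± 0.26, TAGLN by 1.73 ± 0.21 and ACTA2 by 1.68 ± 0.16. For TPM2, a member of this list, tested probe sets were called in both directions. Of 12 endothelial genes 6 were higher, or 7 over the list alone, with a median of 0.86 (adjusted p = 0.000828; adjusted p = 0.411 with an estimated correlation), CDH5 by 2.01 ± 0.31, VWF by 1.81 ± 0.31 and PECAM1 by 1.77 ± 0.23. Of 13 stromal fibroblast genes 5 were higher and 1 lower, or 6 and 2 over the list alone, with a median of 0.75 (adjusted p = 0.00793; adjusted p = 0.239 with an estimated correlation), COL5A1 by 2.50 ± 0.25 and FBLN1 by 1.62 ± 0.23. Without middle replicate 2 the adjusted p was 0.106, the top of a range from 0.000456, and without last replicate 2 the median was 0.49. Of 6 basement membrane genes 3 were higher, or 5 over the list alone, with a median of 0.68 (adjusted p = 0.0053; adjusted p = 0.239 with an estimated correlation), COL4A2 by 1.79 ± 0.16. Of 12 matrix turnover genes 7 were higher, or 9 over the list alone, with a median of 1.07 (adjusted p = 6.44e-05; adjusted p = 0.239 with an estimated correlation), PLAU by 1.92 ± 0.33, MMP14 by 1.36 ± 0.23 and TIMP2 by 1.33 ± 0.20. In the hypoxia and VEGF list 5 of 10 were higher and 0 lower, or 6 and 2 over the list alone, with a median of 0.59 (adjusted p = 0.0104; adjusted p = 0.239 with an estimated correlation), ADM by 3.45 ± 0.32 and ANGPT1 by 2.36 ± 0.27. For this list without middle replicate 2 the adjusted p was 0.0536, the top of a range from 0.00166.

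Of 17 immediate-early and stress genes 14 were higher in the last arrays, also over the list alone, with a median of 1.71 (adjusted p = 2.77e-13; adjusted p = 0.239 with an estimated correlation), ZFP36 by 2.38 ± 0.18. Of 17 genes of endoplasmic reticulum stress and chaperones 9 were higher, or 11 over the list alone, with a median of 0.76 (adjusted p = 6.44e-05; adjusted p = 0.254 with an estimated correlation), ATF4 by 1.28 ± 0.17 and HSPA5 by 0.96 ± 0.13. The 3′ excess of the controls was lower in the last arrays, at 3.73 ± 0.23 for actin and 1.88 ± 0.02 for GAPDH (log2, SD, n = 2), than in the middle arrays, at 4.60 ± 0.54 and 3.04 ± 0.35. The immune list passed with 1 of 17 genes higher, also over the list alone, and a median of 0.96 (adjusted p = 0.00234; adjusted p = 0.676 with an estimated correlation). Its mean level differed between the last arrays, at -1.23 and 0.49 relative to the mean of each gene over the 6 arrays, and its median was 1.92 without last replicate 1 and 0.26 without last replicate 2. Its adjusted p was 0.498 without last replicate 2 and 0.0818 without middle replicate 2, and it was 0.32 by fry, with a range from 6.61e-12. The ribosomal protein list passed with 0 of 55 genes called, also over the list alone, and a median of -0.12 (adjusted p = 0.0053; adjusted p = 0.746 with an estimated correlation). With each array centred on its median the ribosomal list had a median of -0.01 and an adjusted p of 0.191. Without last replicate 1 the median was -0.05 and the adjusted p 0.227, without last replicate 2 the median was -0.18, and the adjusted p was 0.0909 with eBayes without a trend and 0.246 by fry, in a range from 2.31e-05.

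The other 11 lists did not pass. Among granulosa genes 6 of 16 were higher and 5 lower (adjusted p = 0.382), with INHA higher by 2.26 ± 0.26 and AMH at -3.40 ± 0.31. FSHR differed by -1.06 ± 0.23 (adjusted p = 0.0139), and by -1.05 without middle replicate 1 (adjusted p = 0.0974) and -1.07 without middle replicate 2 (adjusted p = 0.0635), over a range of adjusted p from 0.0126 to 0.0974. GDF9 differed by -2.86 ± 0.22 (adjusted p = 6.11e-05). TGF-beta and BMP signalling had 3 of 18 higher and 1 lower (0.705), IGF, insulin and PI3K signalling 1 of 14 higher and 1 lower (0.583), the Hippo, Notch and Wnt list 2 of 9 higher (0.107), mitosis 3 of 18 higher and 1 lower (0.146) and DNA replication 1 of 12 lower (0.283). Antioxidant and detoxification genes had 3 of 24 higher and 3 lower (0.179), apoptosis and atresia 2 of 6 higher and 1 lower (0.35) and complement and acute phase genes 1 of 12 higher and 1 lower (0.831). No gene was called among 31 of oxidative phosphorylation (0.283) or 15 of glycolysis (0.978).

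The comparison of last with primordial follicles set the ends of the series side by side. Most genes of the stromal, theca and smooth muscle lists were higher in the last arrays, and most genes of the immune list were higher in the arrays labelled primordial. With an estimated correlation these lists had an adjusted p of 0.239, and the immune list 0.47. CDH11 was higher in the last arrays by 5.71 ± 0.29 (limma adjusted p = 9.64e-06) and STAR by 5.57 ± 0.31 (adjusted p = 1.42e-05). FABP4 differed by -6.17 ± 0.37 (adjusted p = 1.86e-05) and IL1B by -5.19 ± 0.23 (adjusted p = 9.24e-06). Of 14399 probe sets 4786 (33.2%) were called, 2857 higher and 1929 lower, and of 5432 genes 932 were higher and 857 lower. The count was 2900 without primordial replicate 1 and 2730 without primordial replicate 2, and with each array centred on its median 47.4% of the calls were higher, against 59.7% as deposited.

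Among the other largest increases, the proteoglycans LUM and DCN were higher by 5.38 ± 0.43 and 4.65 ± 0.23, the collagen COL6A3 by 5.21 ± 0.29, the Wnt inhibitor SFRP1 by 5.39 ± 0.27 and the protease ADAMDEC1 by 4.70 ± 0.44. INSL3, a peptide hormone of theca cells, was higher by 4.61 ± 0.29, PTN by 4.60 ± 0.32 and the protease inhibitor A2M by 4.55 ± 0.39. The other largest decreases were AMELX at -5.79 ± 0.51, CCL3L1 at -5.49 ± 0.33, CXCL8 at -5.17 ± 0.24, IL18BP at -4.69 ± 0.26 and CHI3L1 at -4.42 ± 0.49. GPNMB, a glycoprotein of macrophages, differed by -4.70 ± 0.30, ACP5, a lysosomal phosphatase of macrophages and osteoclasts, by -4.63 ± 0.22 and SMPDL3A by -4.47 ± 0.40. The adjusted p was highest for CHI3L1, at 0.000325.

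By camera with its preset correlation 11 of 27 lists passed, 7 higher and 4 lower in the last arrays. With an estimated correlation 0 passed, with 4 at an unadjusted p under 0.05, and fry called 14. Of 13 stromal fibroblast genes 12 were higher, also over the list alone, with a median of 2.77 (adjusted p = 1.73e-08; adjusted p = 0.239 with an estimated correlation), FAP by 4.42 ± 0.29 and COL5A1 by 4.08 ± 0.25. Of 12 smooth muscle and pericyte genes 10 were higher, or 11 over the list alone, with a median of 2.16 (adjusted p = 5.05e-07; adjusted p = 0.239 with an estimated correlation), CNN1 by 3.44 ± 0.26 and TAGLN by 3.33 ± 0.21. Of 12 endothelial genes 9 were higher, also over the list alone, with a median of 1.44 (adjusted p = 0.00204; adjusted p = 0.434 with an estimated correlation), CDH5 by 2.64 ± 0.31. Of 6 basement membrane genes 4 were higher, also over the list alone, with a median of 1.12 (adjusted p = 0.0053; adjusted p = 0.239 with an estimated correlation), NID2 by 2.91 ± 0.33 and LAMB1 by 2.30 ± 0.21. In the theca list 7 of 8 genes were higher and 0 lower, or 7 and 1 over the list alone, with a median of 2.25 (adjusted p = 0.000542; adjusted p = 0.239 with an estimated correlation), CYP17A1 by 3.87 ± 0.40 and LHCGR by 2.16 ± 0.37. In the steroidogenesis list 9 of 16 were higher and 2 lower, or 10 and 3 over the list alone, with a median of 0.76 (adjusted p = 0.0076; adjusted p = 0.449 with an estimated correlation), HSD3B1 by 3.56 ± 0.41. Oxidative phosphorylation had 8 of 31 higher and 2 lower, also over the list alone, with a median of 0.40 (adjusted p = 0.0216; adjusted p = 0.746 with an estimated correlation), UQCRB by 0.87 ± 0.14. For this list the adjusted p was 0.0796 without primordial replicate 1 and 0.109 without last replicate 1, and it was 0.0523 with eBayes without a trend and 0.121 by fry, in a range from 0.0011.

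Of the 4 lists that were lower in the last arrays, the immune list had 13 of 17 genes lower, or 14 over the list alone, with a median of -2.18 (adjusted p = 6.61e-07; adjusted p = 0.47 with an estimated correlation). That median was -1.33 without last replicate 1 and -2.88 without last replicate 2 (adjusted p = 2.15e-06 and 1.76e-13), and fry gave an adjusted p of 0.0759. CD53 differed by -4.21 ± 0.40 and TYROBP by -3.13 ± 0.31. Cholesterol synthesis had 8 of 13 lower, or 10 over the list alone, with a median of -0.90 (adjusted p = 3.75e-05; adjusted p = 0.434 with an estimated correlation), SQLE at -1.96 ± 0.31, NSDHL at -1.86 ± 0.30 and INSIG1 at -1.56 ± 0.21. Endoplasmic reticulum stress and chaperones had 8 of 17 lower, or 12 over the list alone, with a median of -0.65 (adjusted p = 4.91e-05; adjusted p = 0.254 with an estimated correlation), DNAJB9 at -2.08 ± 0.21 and DNAJB11 at -1.48 ± 0.21. Without last replicate 2 the median was -0.37. Glycolysis had 6 of 15 lower and 1 higher, or 7 and 1 over the list alone, with a median of -0.55 (adjusted p = 0.0053; adjusted p = 0.434 with an estimated correlation), SLC2A1 at -1.97 ± 0.23 and LDHA at -1.40 ± 0.24. Without last replicate 2 its median was -0.33 (adjusted p = 0.0284), and fry gave an adjusted p of 0.0633, in a range from 0.00116. The controls of RNA quality differed in direction: the 3′ excess in the last arrays and in those labelled primordial was 1.88 ± 0.02 and 3.06 ± 0.53 for GAPDH, 3.73 ± 0.23 and 3.38 ± 0.25 for actin, and 0.76 ± 0.09 and 0.84 ± 0.24 for EF1A (log2, SD, n = 2). In primordial replicate 2 the poly-A spikes, bacterial transcripts added to the RNA, stood 3.31-fold above the median of the other arrays, and they stood at 0.86 to 1.20 in the others.

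The other 16 lists did not pass. The oocyte list had 2 of 8 genes higher in the last arrays, or 3 over the list alone, and a median of 0.58 (adjusted p = 0.09). GDF9 differed by 0.30 ± 0.22 and ZP3 by 0.64 ± 0.22 (adjusted p = 0.331 and 0.0513), and ZP3 passed with a pseudocount of 1 (0.74, adjusted p = 0.037) and with eBayes without a trend (adjusted p = 0.0439), in a range of 0.037 to 0.304. In the granulosa list 6 of 16 were higher and 2 lower (adjusted p = 0.179), with NR5A2 higher by 1.28 ± 0.24 and INHA at 0.05 ± 0.26 (adjusted p = 0.89), a difference whose sign changed with the scaling. AMH differed by -0.99 ± 0.31 (adjusted p = 0.0346), by -0.77 without primordial replicate 2 (adjusted p = 0.185) and did not pass without any other array of these stages (adjusted p = 0.054 without primordial replicate 1, 0.0998 without last replicate 1, 0.0703 without last replicate 2). AMH also missed the threshold with a pseudocount of 64 (0.0562) and with no filter (0.0687), in a range from 0.022. FSHR differed by -0.93 ± 0.23 (adjusted p = 0.0144), with an adjusted p of 0.0581 without primordial replicate 1 and 0.0788 without primordial replicate 2, in a range from 0.00725. Surface epithelium had 2 of 4 lower (0.146), matrix turnover 2 of 12 higher and 4 lower (0.543), the ovulatory response 3 of 8 higher and 3 lower (0.794), TGF-beta and BMP signalling 5 of 18 higher and 4 lower (0.616), IGF, insulin and PI3K signalling 5 of 14 higher (0.0705) and the Hippo, Notch and Wnt list 3 of 9 higher and 2 lower (0.588). Mitosis had 2 of 18 higher (0.0887), DNA replication 1 of 12 higher (0.483), ribosomal proteins 0 of 55 called (0.822), antioxidant and detoxification genes 5 of 24 higher and 6 lower (0.739), immediate-early and stress genes 1 of 17 higher and 4 lower (0.154), apoptosis and atresia 3 of 6 lower (0.139), hypoxia and VEGF 2 of 10 higher and 2 lower (0.403) and complement and acute phase genes 6 of 12 higher and 3 lower (0.587).

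**Figure D3:**
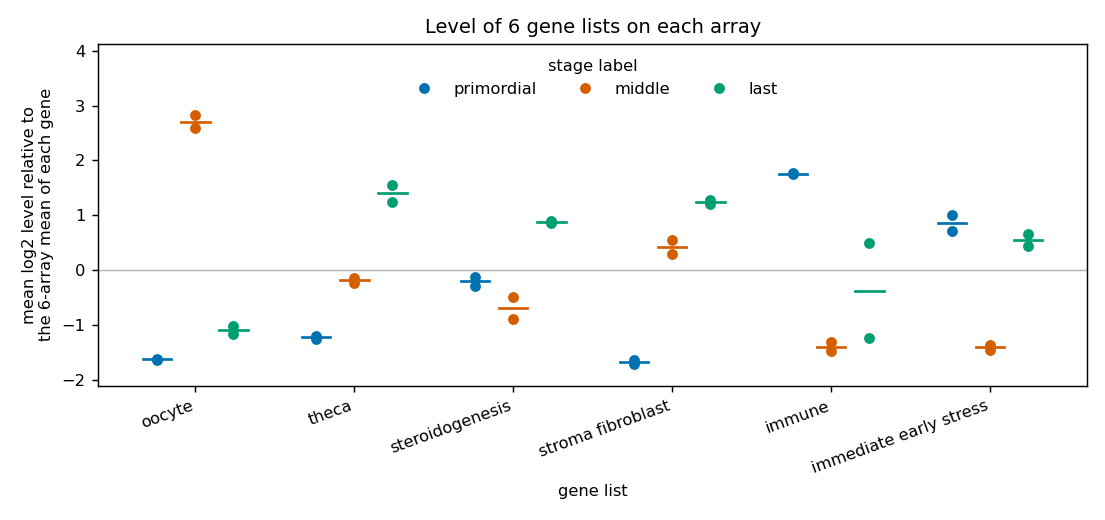
Mean log2 level of 6 gene lists on each array, relative to the mean of each gene over the 6 arrays, with a point for each array and a bar for the mean of the 2 arrays of a stage. The oocyte list stood at 2.59 and 2.82 on the middle arrays and below 0 on the other 4, and the immune list at 1.75 and 1.77 on the arrays labelled primordial.

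The middle stage was also set against the mean of the other stages, to find genes that lay off that mean there. A gene that rises or falls at both steps can lie off it too, so a call alone is not a peak or dip. DPPA5 stood above that mean by 6.17 ± 0.24, ZP4 by 5.48 ± 0.20, ZP2 by 5.42 ± 0.24, KPNA7 by 5.20 ± 0.35 and PADI6 by 5.11 ± 0.36 (limma adjusted p between 1.02e-06 for ZP4 and 1.94e-05 for PADI6). CXCL8 stood below it by the largest amount, at -5.88 ± 0.21, with CCL3L1 at -5.27 ± 0.29, NR5A2 at -5.20 ± 0.21, CCL4 at -4.84 ± 0.23 and RGCC at -4.77 ± 0.49 (adjusted p between 9.74e-07 for CXCL8 and 0.00015 for RGCC). AMH was above the mean by 2.91 ± 0.27 and INHA below it, at -2.23 ± 0.22. Of 14399 probe sets 5399 (37.5%) were called, 3382 above and 2017 below; without middle replicate 1 the count was 2037. With each array centred on its median 46.4% of the calls were above, against 62.6% as deposited.

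Across both steps, 1080 probe sets were higher in middle than in primordial and lower in last than in middle, and 671 went the opposite way, while 76 were higher at both steps and 35 lower at both. Independent lists of these sizes would share 425, 186, 312 and 253. Both steps use the middle arrays, so their differences were tied by chance: the correlation across probe sets was -0.63, against -0.50 in 20 simulations without effects, and the covariance was -0.63 against -0.05. At both steps 1862 probe sets were called, against a mean of 0 in those simulations. With no effects hardly any probe set is called at either step. That mean of 0 therefore cannot measure what the shared arrays add. Part of the excess over independent lists may come from the shared middle arrays, which are too few to split.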

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

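All alternatives here were chosen before the data were seen, except the list count of last minus middle from 4 arrays, chosen after the data were seen. Signals of 16 or less, 12.8% to 18.0% of probe sets per array, lie where the pseudocount limits the fold. The 334 single-gene results were each recomputed under several alternatives. Of the recomputed values, 4675 kept their sign and their side of the threshold, 264 lost the threshold and 3 gained it without a change of sign. In 4 values the sign changed, all of differences that were not called. These were FSHR in middle minus primordial with quantile normalization (-0.17) and with each array centred on its median (-0.11), and INHA in last minus primordial with each array centred on its median (-0.079) and without primordial replicate 1 (-0.22, against 0.33 without primordial replicate 2). Centring takes the same amount from each gene of an array, so small differences change sign. Without primordial replicate 1, INHA in the last arrays, at 14359 and 13618, was set against primordial replicate 2 alone, at 16319. The cause of the FSHR change with quantile normalization was not tested. Of 36 list calls none changed direction. Of their recomputed values 560 kept the call and 67 lost it, 36 of these with an estimated correlation.

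With a minimum difference of 2-fold, 4512 probe sets were called in middle minus primordial and 2930 in last minus primordial. Over the fits without 1 array, counts ran from 4356 to 7189 in middle minus primordial, 727 to 2172 in last minus middle, 2730 to 4297 in last minus primordial, 2037 to 5320 for the middle stage against the mean of the others and 4952 to 7354 for any stage difference. Which array was left out mattered: last minus middle gave 727 without middle replicate 1, and 1891 and 1947 without last replicates 1 and 2. List counts ran from 8 to 10, 12 to 17 and 10 to 14. With an estimated correlation 0 lists passed in all 3 comparisons, and fry called 14 in middle minus primordial; the cause was not tested.

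Arrays with the same replicate number hardly deviated together across probe sets. The correlation of the replicate differences was 0.03 between primordial and middle, 0.00 between middle and last and 0.03 between primordial and last. These correlations cannot show whether arrays with the same number shared an animal or a batch. With a replicate block 6601, 2279 and 4532 probe sets were called in the 3 comparisons. The last minus middle comparison without both arrays labelled primordial gave 2196 probe sets, and 16 lists in a fit chosen after seeing the data; the other comparisons need those arrays.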

Other observations

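The gene lists and tests in this part were chosen after the data were seen. The p-values of these later lists were adjusted over these lists and the 3 pairwise comparisons only, apart from the lists fixed in advance. Lysosomal genes were lower outside the arrays labelled primordial: 20 of 23 in the middle arrays, with a median of -1.32 (camera adjusted p = 4.19e-09; adjusted p = 0.382 with an estimated correlation), and 15 of 23 in the last arrays, with a median of -0.88 (adjusted p = 4.19e-09; adjusted p = 0.382 with an estimated correlation). In last minus primordial the cathepsins CTSZ, CTSH and CTSD differed by -3.26 ± 0.26, -2.69 ± 0.25 and -2.27 ± 0.21, and the cholesterol transporter NPC1 by -2.05 ± 0.22. Of 13 cytokine genes 10 were lower and 2 higher in the middle arrays than in those labelled primordial (median -3.67, adjusted p = 0.000201; adjusted p = 0.382 with an estimated correlation), and 8 were lower and 2 higher in the last arrays (adjusted p = 0.00298; adjusted p = 0.382 with an estimated correlation). In last minus primordial CXCL14 differed by -4.23 ± 0.26 and IL1A by -3.88 ± 0.26, whereas CXCL12, a chemokine of stromal cells, was higher by 3.85 ± 0.44. In last minus middle 4 of 23 lysosomal genes were higher (adjusted p = 0.00261; adjusted p = 0.624 with an estimated correlation) and 6 of 13 cytokine genes (adjusted p = 0.000439; adjusted p = 0.382 with an estimated correlation), and 0 were lower.

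Proteasome genes were lower in the middle arrays than in those labelled primordial for 10 of 29 (median -0.34, adjusted p = 0.00298; adjusted p = 0.624 with an estimated correlation), higher in the last than the middle arrays for 2 of 29 (adjusted p = 0.003; adjusted p = 0.624 with an estimated correlation), and lower in last minus primordial for 4 of 29 (adjusted p = 0.276). Of 21 interferon response genes 8 were lower and 1 higher in middle minus primordial (adjusted p = 0.0544), 4 were higher in last minus middle (adjusted p = 0.00521; adjusted p = 0.663 with an estimated correlation) and 1 was higher and 2 lower in last minus primordial (adjusted p = 0.992). Of 3 cilium genes, too few to test as a list, 1 was higher and 1 lower in each comparison.

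Oocyte transcripts were low in the arrays labelled primordial, where ZP2, ZP3, ZP4 and GDF9 had mean signals of 22.4, 71.4, 53.5 and 144, against 2000, 2531, 4196 and 1414 in the middle arrays; against the last arrays the oocyte list did not pass (2 of 8 genes higher there, adjusted p = 0.09). An exchange of the primordial and last labels is argued against by the theca list, whose median was higher by 2.25 in the arrays labelled last, with 7 of 8 genes higher. An exchange of the primordial and middle labels cannot be told apart from the labels as given: AMH, expected in growing rather than primordial follicles, was higher by 2.41 ± 0.31 in the arrays labelled middle, which goes against it, while INHA, CYP19A3 and HSD17B1, genes of larger follicles, had a median of -2.20 there, which goes with it. Of the lists that ran with the labels as given, theca had a median of 1.53 and 5 of 8 genes higher and 1 lower but did not pass (adjusted p = 0.131), and the stromal list had a median of 2.01 and 9 of 13 higher (adjusted p = 0.00015; adjusted p = 0.239 with an estimated correlation). Lists that ran the other way included the ovulatory response, with a median of -1.22, and steroidogenesis, with a median of -0.46. The ovulatory response had 4 of 8 genes lower and 2 higher (camera adjusted p = 0.0445, and 0.434 with an estimated correlation). That call was lost under several alternatives. Steroidogenesis, which holds CYP19A3 and HSD17B1, had 7 of 16 lower and 3 higher and did not pass (camera adjusted p = 0.283). A difference between the stages themselves, or in how they were isolated, stays open and was not tested.

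Immune transcripts were high in the arrays labelled primordial, with the immune list at 1.75 and 1.77 relative to the mean of each gene, and the last arrays differed from each other, at -1.23 and 0.49. A smaller share of granulosa cells alone is argued against by the stromal list, whose median was higher by 2.77 in the last arrays, since that share would raise the markers of every other cell type. RNA of macrophages is a candidate source: of 21 tested genes of a macrophage list that shares 0 genes with the immune list, 18 were lower in last minus primordial and 19 in middle minus primordial (camera adjusted p = 3.2e-09 and 4.19e-09; adjusted p = 0.393 with an estimated correlation in both; 13 to 17 and 18 to 19 lower without each array in turn), and in last minus primordial its genes with the brightest probe sets, CTSS, CD83, FCGRT and APOE, differed by -2.10, -2.29, -0.64 and -1.64. Their mean signals in the arrays labelled primordial were 13266, 6010, 5883 and 5828, which do not rank abundance between genes. In the last arrays 19 of the list's genes were also above the filter level, and the labels name no sort, only isolation by morphology and diameter. The macrophage list was chosen after the immune pattern was seen on these same arrays. Its 0 shared genes therefore do not make it independent support. RNA of lymphocytes stays open, with 4 of 6 tested genes lower in middle minus primordial and 2 lower and 1 higher in last minus primordial, too few to decide; the first rule, at most 3 of 6 lower in last minus primordial, counted against lymphocytes and was replaced after the count was seen, and inflammation of the follicles themselves was not tested.

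Immediate-early and stress genes were low in the middle arrays against both other stages. The scaling of the arrays is argued against as the whole cause by the size of the differences. With quantile normalization the list's median was -1.555 in middle minus primordial and 1.544 in last minus middle. Over all probe sets tested, as deposited, the medians were 0.22 and -0.07. The list also kept its calls with quantile normalization, the highest adjusted p being 1.24e-08 by camera with its preset correlation. Camera compares a list with the other genes, so a factor shared by a whole array weighs little in it. With an estimated correlation and the deposited scaling the adjusted p was 0.239 in both. Loss of RNA quality in the middle arrays cannot be told apart from a stage difference: the 3′ excess was highest in the middle arrays for 2 of 3 control transcripts, actin and EF1A, and not for GAPDH, and for EF1A the middle arrays, at 1.10 ± 0.33 (SD, n = 2), were within the spread of those labelled primordial, at 0.84 ± 0.24. The stage, and the time and handling before RNA extraction, which are not given in the sources used here, stay open and were not tested.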
